A study of Rattus norvegicus with 17 samples.

How the data were processed

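Messenger RNA was measured in 17 libraries of rat primary cortical cultures holding glutamatergic neurons and astrocytes. The cultures carried either an empty vector or the A53T variant of α-synuclein, the presynaptic protein that aggregates in Parkinson's disease. Each was given the solvent DMSO or FK506 at 0.2 or 2.0 µM, doses that the labels call below saturation and saturating. FK506 binds the immunophilin FKBP12 and so inhibits the calcium-dependent phosphatase calcineurin. The labels place 3 libraries in each of the 6 groups except A53T in DMSO, which has 2. The titles number these 2 samples 1 and 2, while their columns in the deposited table carry 1 and 3, so the second column was used as a replicate without a number.

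Per the labels' protocols, libraries were made with a stranded mRNA kit. FastQC, TopHat and HTSeq and the rat build rn6 are named in the submitters' processing notes, and their versions were not given in the sources used here. The deposited values are gene counts that the authors normalized, which were treated here as a signal and not as whole reads, since the normalization method was not given in the sources used here. At a tolerance of 0.1 step, at least 95% of the low values were whole multiples of a single step in 3 of the 9 libraries that had the 100 low values needed for this check. Whole reads were therefore not recovered, and the count test planned for that case was not run. The deposited table held 11247 gene labels, of which 10458 matched a current symbol in a RefSeq table of a later build, GRCr8, and 11093 matched a symbol or synonym; that table was used for names only. A further 23 labels looked like dates and were never named. Normalized totals ran from 15091428 to 18335540 per library, and the raw depth is unknown, so no interval for counting error is given.

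Replicates were compared before averaging. For genes with mean values from 10 to 3000, the median squared difference of each pair was set against Poisson sampling. The 3 libraries of A53T at 0.2 µM differed by 0.988 to 1.05 times the sampling noise. Pairs in the other groups differed by 1.48 to 14.4 times. The only pair of A53T in DMSO differed by 1.69 times, and the closest pair by 1.715 in vector at 0.2 µM and 1.478 at 2.0 µM. These lie not far above sampling noise, and their libraries were still counted as separate samples. For means from 3000 to 10000 the A53T libraries at 0.2 µM had ratios of 1.14 to 1.60, and above 10000 of 1.95 to 3.59. There they exceeded sampling noise, while pairs in the other groups had at least 2.885 and 8.64. These ratios treat the normalized values as counts, so the noise level is approximate. The contrast between groups on the same scale was what decided. The 3 libraries of A53T at 0.2 µM were therefore counted as 1 sample by their mean, which left 15 samples and 9 residual degrees of freedom. The lone sample is assumed to vary like the samples of the other groups. The design fixed before the data were examined had all 17 libraries in the fit, and that fit is kept as an alternative chosen afterwards. Nothing says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

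Values were analysed as log2(value + 1) with limma 3.58.1 (trend=TRUE) in R 4.3.3, in 1 fit with a mean per group and 11 contrasts, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The minimum mean value of 1 removed 0 genes, and the lowest mean in the table was 3.65. A list of 43 gene sets (pathways, cell type markers and quality sets) was fixed before the data were examined, and 41 had at least 3 measured members. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over 451 pairs of list and contrast, and again with an estimated correlation and with fry. With the estimated correlation 0 of the 451 pairs passed, and the smallest adjusted p was 0.135; with the preset one 177 pairs passed, and with fry, which asks only whether a set's own genes move on balance in 1 direction, 297 passed.

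Genes were named by a rule fixed beforehand. It takes the study genes (calcineurin subunits and their partners), the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 and no overlap between the groups (4 and 4 for dose and interaction contrasts), and at most 4 members of each list by smallest p. A total of 333 labels without a gene name were tested and not named. Some results for single genes are not reported here.

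The deviations of the 14 libraries outside A53T at 0.2 µM from their group means shared a leading axis, which held 54.2% of the within-group variance. Every library was scored on it, with the mean of vector in DMSO at 0 and the sign set so that A53T at 0.2 µM was positive. Alternatives fixed beforehand were pseudocounts of 0.25 and 4, no filter or a mean of at least 10, rescaling by median-of-ratios size factors, quantile normalization, only the groups compared, a replicate block, trend=FALSE, an estimated list correlation and each library left out in turn. The alternatives chosen after the data were seen were the 17-library fit, the axis score as a covariate, a fit without the 3 libraries that stood apart on the axis, and a block with the numbers in the table's column names.

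The procedure was tested on simulated data with 200 changed genes among 11247 in 10 draws, with the axis as shared noise. For 2.0 µM against DMSO in vector, 55.5% of genes changed 1.5-fold, 79.5% of those changed 2-fold and 93.8% of those changed 4-fold were recovered. For 0.2 µM against DMSO in A53T, where 1 sample met 2, the shares were 30.9%, 63.9% and 85.0%. False calls had a median of 1 gene for A53T against vector at 2.0 µM, but a single draw gave 2996, since libraries that differ along the axis change many genes together. The simulation gave every library the same spread along the axis. The comparisons within vector, with at most 8 false calls in these draws, therefore carry the same risk. With the axis as covariate the highest number of false calls in that comparison was 15. In the same simulations, with no gene list changed, a median of 36 and at most 56 of the 451 list pairs passed camera with the preset correlation.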

Results

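Rat primary cortical cultures of glutamatergic neurons and astrocytes carried an empty vector or α-synuclein A53T and were given DMSO, 0.2 µM FK506 or 2.0 µM FK506. FK506 inhibits calcineurin, a phosphatase that calcium activates. Values were read for 11247 genes in 17 libraries, 3 per group except A53T in DMSO with 2. The 3 libraries of A53T at 0.2 µM agreed within sampling noise, as far as normalized values show it: they differed by 0.988 to 1.05 times the Poisson noise of counts of that size, against 1.48 to 14.4 times in the other groups. They were counted as 1 sample. The 2 libraries of A53T in DMSO differed by 1.69 times, not far above that noise, and were kept as 2 samples. The value after a gene is its log2 fold change ± standard error from limma, and "rose" and "fell" are used only for genes past an adjusted p of 0.05 over all genes.

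Libraries also varied along an axis within groups. The 3 libraries of A53T at 0.2 µM scored from 4.98 to 5.02 on it, and the other 14 from -2.42 to 1.52. Replicate 1 of vector at 0.2 µM, replicate 2 of vector at 2.0 µM and replicate 1 of A53T at 2.0 µM stood apart from their own groups. Counts are also given without these 3 libraries. They were picked for their deviation, so leaving them out lowers the spread and favours higher counts, which are no check of the results.

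**Figure D1:**
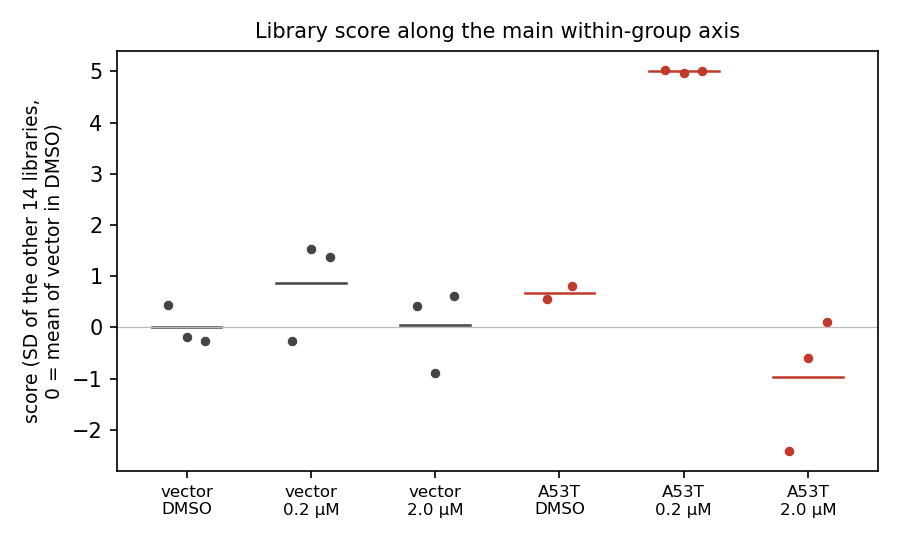
Score of each of the 17 libraries (points) along the leading within-group axis, by group, with lines at group means. The 3 A53T libraries at 0.2 µM lie between 4.98 and 5.02, and the other 14 lie between -2.42 and 1.52.

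Among genes of the calcineurin pathway, the regulator Rcan2 fell in vector at both doses (-0.60 ± 0.05 and -0.85 ± 0.05). The catalytic subunit Ppp3ca fell at 2.0 µM in vector (-0.69 ± 0.16) and in A53T (-0.73 ± 0.18), as did Nfatc2, a transcription factor that calcineurin activates (-1.45 ± 0.29 and -2.38 ± 0.32). Nfatc3, of the same family, rose in both (0.99 ± 0.11 and 0.50 ± 0.12). In A53T neither Ppp3ca (adjusted p = 0.0513) nor Nfatc3 (adjusted p = 0.0638) passed in a fit of only the groups compared.

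**Figure D2:**
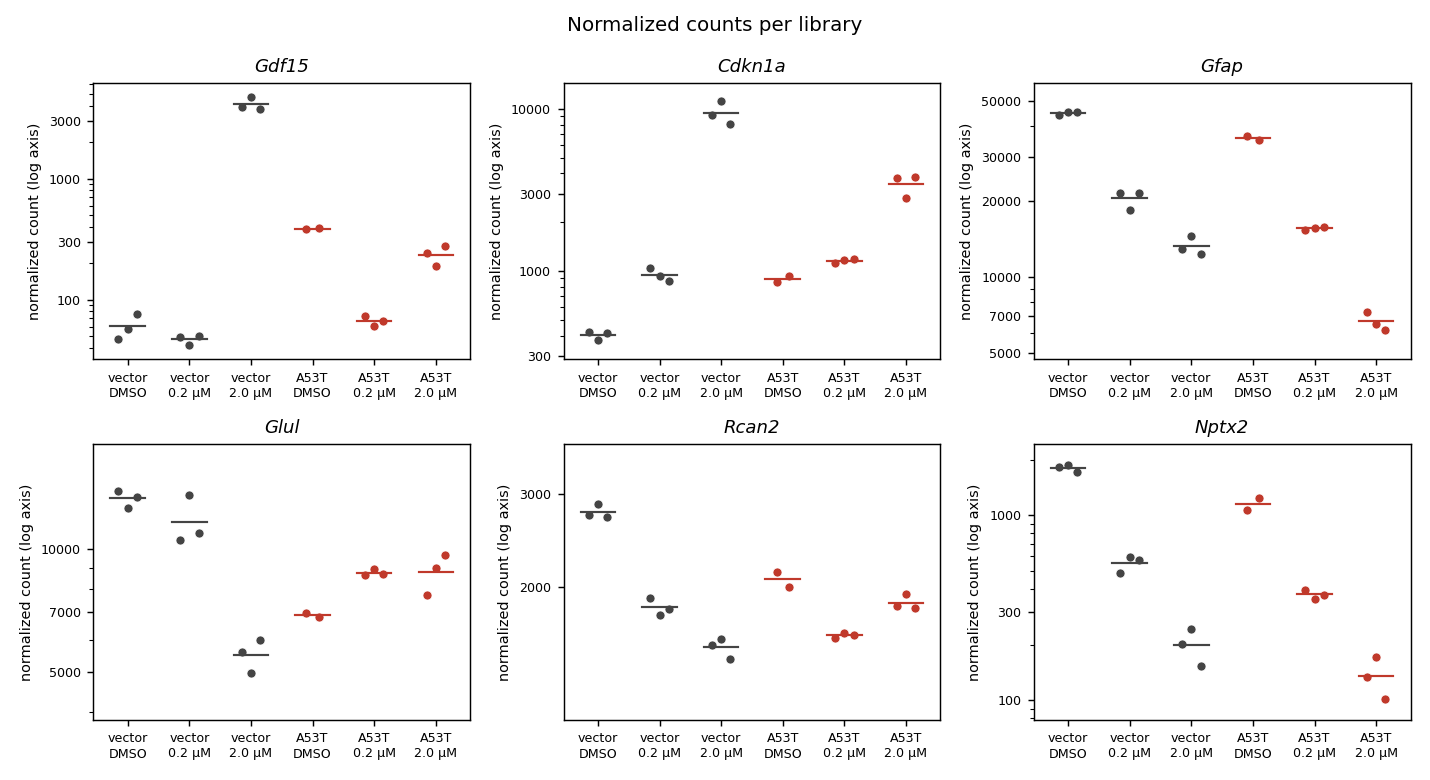
Normalized counts per library (points, logarithmic vertical axes that differ between panels) of Gdf15, Cdkn1a, Gfap, Glul, Rcan2 and Nptx2 by group, with lines at group means. Gdf15 averaged 4144 in vector at 2.0 µM and 236 in A53T at 2.0 µM, and the 3 A53T libraries at 0.2 µM were counted as 1 sample in tests.

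A53T in DMSO differed from vector in stress genes and neuropeptides. The secreted stress cytokine Gdf15 rose (2.69 ± 0.19, adjusted p = 1.1e-05), as did the cell cycle inhibitor Cdkn1a (1.14 ± 0.14) and St8sia2, which builds polysialic acid chains (2.11 ± 0.28). The matrix proteoglycan Lum (-3.37 ± 0.35) and the interneuron peptide Cort (-2.90 ± 0.37) fell. Fibroblast and meningeal markers fell in 6 of 13 cases and rose in 1 (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.14 with an estimated correlation). Of 18 measured p53 and apoptosis genes 8 rose and 0 fell (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.14 with an estimated correlation), including the proapoptotic Hrk (1.34 ± 0.06) and Gadd45a (0.79 ± 0.12). Of 23 activity-dependent early genes 8 rose and 1 fell (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 5.2e-04, adjusted p = 0.43 with an estimated correlation), such as Fosb (1.53 ± 0.25) and Fos (0.89 ± 0.17, or adjusted p = 0.0703 with a replicate block by title numbers).

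Secreted peptides, interneuron markers and metabolic genes were lower. Neuropeptide and trophic factor genes fell in 9 of 18 cases and rose in 0 (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.14 with an estimated correlation), among them Vgf (-1.12 ± 0.12) and Vip (-2.11 ± 0.27). GABAergic interneuron markers fell in 6 of 16 cases and rose in 0 (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 8.1e-04, adjusted p = 0.27 with an estimated correlation), with the vesicular GABA transporter Slc32a1 (-0.64 ± 0.06) and Sst (-1.21 ± 0.17). Glycolysis genes fell in 12 of 21 cases and rose in 0 (2 higher and 14 lower adjusted over the list alone, camera adjusted p = 2.0e-04, adjusted p = 0.25 with an estimated correlation), including Aldoc (-0.60 ± 0.11, or adjusted p = 0.0524 with that block). Cholesterol synthesis genes fell in 8 of 21 cases and rose in 0 (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.14 with an estimated correlation), including the squalene synthase Fdft1 (-0.66 ± 0.09). In total 658 genes were higher and 921 lower, and 60.4% of genes had no overlap between the groups, against 20% by chance. The chance share is an average for exchangeable libraries. Genes vary together along the axis, so a share far from it can also arise without an effect. The same limit holds for the shares given below. With the 3 libraries that stood apart removed, 2125 and 2265 genes passed, and with replicate 1 of A53T in DMSO left out only 413 did. A replicate block by title numbers gave fewer genes, but it also leaves out the unnumbered library, so A53T in DMSO keeps 1 sample. A block by column numbers, which keeps every library, gave 1162.

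FK506 at 0.2 µM in vector lowered astrocyte genes, neuropeptide genes and some neuron markers. The astrocyte filament Gfap fell (-1.13 ± 0.08, adjusted p = 1.8e-05), from 44906 ± 699 to 20606 ± 1759 normalized counts (mean ± SD, n = 3 each). The citrate transporter Slc13a5 (-3.53 ± 0.44), the actin-linked adaptor Pstpip1 (-2.55 ± 0.28) and the microRNA gene Mir212 (-2.38 ± 0.32) fell too. St8sia2 (1.68 ± 0.25) and the metalloprotease Mmp12 (1.63 ± 0.29) rose. Reactive astrocyte genes fell in 11 of 22 cases and rose in 0 (0 higher and 15 lower adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.14 with an estimated correlation), with the copper carrier Cp (-1.07 ± 0.11) and the filament Vim (-0.77 ± 0.12). General astrocyte markers fell in 7 of 19 cases and rose in 0 (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 5.3e-04, adjusted p = 0.14 with an estimated correlation). Pan-neuronal markers also fell in 7 of 19 and rose in 0 (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0076, adjusted p = 0.25 with an estimated correlation). GABAergic interneuron markers fell in 4 of 16 cases and rose in 0 (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0078, adjusted p = 0.36 with an estimated correlation). The quality list of housekeeping genes fell in 4 of 12 cases and rose in 1 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.31 with an estimated correlation). After quantile normalization neither pan-neuronal markers (camera adjusted p = 0.386) nor housekeeping genes (camera adjusted p = 0.498) passed. The GABAergic markers did not pass without replicate 1 of vector at 0.2 µM (camera adjusted p = 0.0832).

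Of 18 neuropeptide and trophic factor genes 10 fell and 2 rose (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.14 with an estimated correlation), including the opioid precursor Penk (-1.97 ± 0.17) and the neurotrophin Bdnf (-1.30 ± 0.12). Oxidative phosphorylation genes fell in 11 of 22 cases and rose in 0 (0 higher and 19 lower adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.37 with an estimated correlation), such as Atp5a1 (-0.24 ± 0.05, or -0.07 and not passed after quantile normalization). Across genes the fold changes and the axis loadings had r = 0.52, and the median of this list went from -0.37 to -0.24 with the axis score as covariate. Glycolysis genes fell in 14 of 21 cases and rose in 0 (1 higher and 15 lower adjusted over the list alone, camera adjusted p = 8.2e-06, adjusted p = 0.16 with an estimated correlation), including Ldha (-0.59 ± 0.09). Cholesterol synthesis genes fell in 8 of 21 cases and rose in 0 (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.14 with an estimated correlation), with the sterol oxidase Msmo1 (-0.83 ± 0.06). Overall 866 genes rose and 1190 fell, and 38.7% had no overlap, against 10% by chance. Without the 3 libraries that stood apart the counts were 2819 and 3078. The library of vector at 0.2 µM left out there scored -0.27 on the axis, and those kept scored 1.38 and 1.52. Vector in DMSO averaged 0, so these higher counts can hold variation along the axis. Leaving out 1 library gave from 980 to 2916 genes, and a replicate block by title numbers gave 1307.

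At 2.0 µM in vector, stress genes rose. Gdf15 (6.10 ± 0.17) and Cdkn1a (4.53 ± 0.13) had the largest rises (adjusted p = 4.0e-10 for each), and Gdf15 went from 60.1 ± 14.2 to 4144 ± 543 normalized counts (mean ± SD, n = 3 each). The thyroid hormone deiodinase Dio2 (3.77 ± 0.20) and the cytokine Lif (3.08 ± 0.62) also rose. Crhbp, which binds corticotropin-releasing hormone (-3.44 ± 0.18), and Slc13a5 (-3.38 ± 0.44) fell. Of 18 p53 and apoptosis genes 12 rose and 1 fell (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.2e-06, adjusted p = 0.14 with an estimated correlation), including Ccng1 (1.12 ± 0.05) and Aen (0.98 ± 0.08). The unfolded protein and integrated stress responses had 19 of 24 genes higher and 0 lower (20 higher and 0 lower adjusted over the list alone, camera adjusted p = 9.7e-07, adjusted p = 0.20 with an estimated correlation), with the transcription factor Atf3 (2.30 ± 0.11) and the chaperone Hspa5 (1.13 ± 0.07). Heat shock genes rose in 8 of 17 cases and fell in 1 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0079, adjusted p = 0.32 with an estimated correlation), led by Cryab (2.67 ± 0.19).

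Cell type markers and neuropeptide genes fell in the same cultures. Astrocyte markers fell in 14 of 19 cases and rose in 2 (2 higher and 15 lower adjusted over the list alone, camera adjusted p = 9.7e-05, adjusted p = 0.14 with an estimated correlation), with Gfap (-1.76 ± 0.08), the glutamate carrier Slc25a18 (-2.02 ± 0.11) and the glutamate transporter Slc1a3 (-0.92 ± 0.07). GABAergic interneuron markers fell in 11 of 16 cases and rose in 0 (0 higher and 12 lower adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.18 with an estimated correlation), including Gad1, which makes GABA (-1.44 ± 0.08). Pan-neuronal markers fell in 12 of 19 cases and rose in 0 (0 higher and 14 lower adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.14 with an estimated correlation). Cytosolic ribosomal protein genes, a quality list, rose in 7 of 24 cases and fell in 0 (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.74 with an estimated correlation). Of them 21 rose with the axis as covariate. Without replicate 2 of vector at 2.0 µM this list did not pass (camera adjusted p = 0.197). Neuropeptide and trophic factor genes fell in 12 of 18 cases and rose in 1 (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.14 with an estimated correlation), with the pentraxin Nptx2 (-3.20 ± 0.18) and Bdnf (-1.96 ± 0.12). In total 2635 genes rose and 2672 fell, and 60.5% had no overlap, against 10% by chance. The counts were 3471 and 3414 without the 3 libraries that stood apart. Set against 0.2 µM in vector, 2.0 µM raised Gdf15 (6.42 ± 0.17), the Nrf2 targets Osgin1 (2.04 ± 0.13) and Hmox1 (1.73 ± 0.11) and the sterol gene Msmo1 (1.09 ± 0.06), and 2021 genes were higher and 1764 lower (2823 and 2579 without those libraries).

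In A53T cultures, 2.0 µM FK506 lowered reactive astrocyte, complement and synaptic genes and raised stress response genes. Gfap fell (-2.42 ± 0.09, adjusted p = 1.9e-08), as did Vim (-2.21 ± 0.13), the matrix protein Thbs4 (-3.31 ± 0.20) and Nptx2 (-3.11 ± 0.21), while Dio2 rose (2.71 ± 0.22). Reactive astrocyte genes fell in 15 of 22 cases and rose in 2 (2 higher and 16 lower adjusted over the list alone, camera adjusted p = 4.5e-07, adjusted p = 0.14 with an estimated correlation), including the lipid receptor S1pr3 (-2.10 ± 0.15). All 7 measured complement genes fell (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.14 with an estimated correlation), among them Serping1 (-1.57 ± 0.09) and C2 (-1.61 ± 0.13). The unfolded protein and integrated stress responses had 18 of 24 genes higher and 0 lower (19 higher and 0 lower adjusted over the list alone, camera adjusted p = 3.4e-08, adjusted p = 0.14 with an estimated correlation), such as Herpud1 (0.90 ± 0.07) and Hspa5 (0.81 ± 0.08). Activity-dependent early genes fell in 15 of 23 cases and rose in 3 (4 higher and 17 lower adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.37 with an estimated correlation), with Bdnf lower (-1.30 ± 0.14) and Jun higher (0.57 ± 0.06).

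Postsynaptic genes fell in 15 of 24 cases and rose in 0 (0 higher and 17 lower adjusted over the list alone, camera adjusted p = 2.8e-06, adjusted p = 0.34 with an estimated correlation), with the scaffold Shank3 (-0.68 ± 0.08). Presynaptic vesicle genes fell in 16 of 25 cases and rose in 1 (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 9.7e-06, adjusted p = 0.15 with an estimated correlation), with Vamp1 (-0.62 ± 0.06) and Bsn (-0.55 ± 0.08). Neuron markers fell too. Glutamatergic markers fell in 10 of 18 cases and rose in 0 (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.25 with an estimated correlation). GABAergic markers fell in 10 of 16 cases and rose in 0 (0 higher and 10 lower adjusted over the list alone, camera adjusted p = 3.5e-04, adjusted p = 0.25 with an estimated correlation). Pan-neuronal markers fell in 7 of 19 cases and rose in 1 (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.32 with an estimated correlation). The pan-neuronal list did not pass with replicate 3 of A53T at 2.0 µM left out (camera adjusted p = 0.0505). Cytosolic ribosomal protein genes, a quality list, rose in 15 of 24 cases and fell in 0 (21 higher and 0 lower adjusted over the list alone, camera adjusted p = 8.9e-05, adjusted p = 0.59 with an estimated correlation). Their median went from 0.50 to 0.10 with the axis as covariate. The axis scores of the groups also differed (mean -0.97 against 0.68), and with the score as covariate the postsynaptic median went from -0.64 to -0.38. Overall 2215 genes rose and 2018 fell, and 64.5% had no overlap, against 20% by chance. Without the 3 libraries that stood apart the counts were 2812 and 2625. Leaving out 1 library gave from 1837 to 4880 genes, and a replicate block by title numbers gave 1574. That block also leaves out the unnumbered library of A53T in DMSO, and a block by column numbers, which keeps every library, gave 3916. A fit of only the groups compared gave 1786, and the highest of 10 simulated draws gave 3365 false calls. The simulation treated all groups alike, so this risk is not particular to this comparison.

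The 1 sample of A53T at 0.2 µM stood far from every other group, with ion channel genes higher and ribosomal and energy genes lower. Tests of it assume that it varies like samples of the other groups. Against DMSO in A53T, voltage-gated channel genes rose in 20 of 22 cases and fell in 1 (20 higher and 2 lower adjusted over the list alone, camera adjusted p = 7.5e-06, adjusted p = 0.36 with an estimated correlation), led by the calcium channel Cacna1e (5.43 ± 0.38) and the potassium channel Kcnq3 (5.31 ± 0.32). All 24 measured ribosomal protein genes fell (0 higher and 24 lower adjusted over the list alone, camera adjusted p = 1.0e-06, adjusted p = 0.50 with an estimated correlation), including Rpl10a (-1.24 ± 0.19). Housekeeping genes, like the ribosomal ones a quality list, fell in 8 of 12 cases and rose in 0 (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.24 with an estimated correlation). This list did not pass after quantile normalization (camera adjusted p = 0.0902). Oxidative phosphorylation genes fell in 20 of 22 cases and rose in 0 (0 higher and 21 lower adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.41 with an estimated correlation), including Atp5a1 (-0.61 ± 0.07). Gdf15 (-2.51 ± 0.26), the stress sensor Gadd45b (-2.85 ± 0.25) and Penk (-2.12 ± 0.25) fell. These lists moved with the axis: across genes the fold changes and the axis loadings had r = 0.79, and with the score as covariate the ribosomal median went from -1.33 to -0.29 and the channel median from 1.95 to 0.77.

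The counts were 3778 higher and 3850 lower against DMSO in A53T (1485 and 1832 with the axis as covariate). Against vector at 0.2 µM they were 3803 and 3943 (1539 and 1699), with Cacna1e higher (4.99 ± 0.35) and the complement factor Cfb lower (-3.53 ± 0.36). At 2.0 against 0.2 µM in A53T 4358 genes were higher and 4334 lower (748 and 947), with Kcnq3 lower (-4.70 ± 0.30). Without the 3 libraries that stood apart the counts were 4250 and 4180, 4068 and 4020 and 4422 and 4366. Quantile normalization moved the median gene by -0.204, -0.195 and 0.247 in these comparisons. It turned the near-equal counts into 3292 and 4820, then 3276 and 4959, then 5305 and 3745. The balance of directions thus depended on the scaling. The interaction at 0.2 µM, the change in A53T minus that in vector, was positive for 2491 genes and negative for 2830, or 46.8% positive, and 35.8% positive after quantile normalization (median shift -0.186). Without the 3 libraries the counts were 3348 and 3236. The axis covariate gave 1183 and 1023, and a replicate block by title numbers 1153 and 568. Cacna1e had an interaction of 4.69 ± 0.45 and Gdf15 of -2.19 ± 0.31.

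At 2.0 µM, A53T had lower inflammatory and reactive astrocyte genes than vector (n = 3 each). Gdf15 was lower (-4.14 ± 0.17, adjusted p = 4.9e-08), as were the smooth muscle protein Tagln (-2.49 ± 0.17), the early gene Fosl2 (-2.63 ± 0.18) and Cfb (-2.74 ± 0.25). The metalloprotease inhibitor Timp4 (2.33 ± 0.14) and the NMDA receptor subunit Grin2c (2.14 ± 0.19) were higher. Complement genes were lower in 5 of 7 cases and higher in 0 (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 7.7e-06, adjusted p = 0.14 with an estimated correlation). NF-kB and cytokine genes were lower in 6 of 8 cases and higher in 0 (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 3.2e-05, adjusted p = 0.14 with an estimated correlation), such as the adhesion molecule Icam1 (-1.37 ± 0.15) and the chemokine Cxcl1 (-1.23 ± 0.25). Reactive astrocyte genes were lower in 11 of 22 cases and higher in 0 (0 higher and 12 lower adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.14 with an estimated correlation), with Gfap (-0.99 ± 0.08) and the hyaluronan receptor Cd44 (-1.10 ± 0.13). Astrocyte markers were higher in 9 of 19 cases and lower in 3 (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.14 with an estimated correlation). Fibroblast and meningeal markers were lower in 5 of 13 cases and higher in 1 (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0074, adjusted p = 0.14 with an estimated correlation). Extracellular matrix genes were lower in 6 of 19 cases and higher in 0 (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.14 with an estimated correlation). After quantile normalization the astrocyte marker list did not pass (camera adjusted p = 0.18). The extracellular matrix list of A53T against vector at 2.0 µM did not pass either (camera adjusted p = 0.0724). Fold changes and axis loadings had r = -0.51 across genes, with group means on the axis of -0.97 in A53T and 0.05 in vector. With the score as covariate the astrocyte marker median went from 0.16 to 0.49. Ribosomal protein genes, a quality list, had 1 of 24 higher and 0 lower (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.64 with an estimated correlation). The ribosomal median went from 0.27 to 0.03 with that covariate, and the list did not pass (camera adjusted p = 0.245).

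Heat shock genes were lower in 8 of 17 cases and higher in 0 (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 3.5e-04, adjusted p = 0.20 with an estimated correlation), including Hspa1b (-0.80 ± 0.07). Genes for glutamate and lactate supply by astrocytes were higher in 9 of 21 cases and lower in 2 (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.9e-04, adjusted p = 0.14 with an estimated correlation), including the glycogen phosphorylase Pygm (1.13 ± 0.07) and the glutamine transporter Slc38a3 (0.92 ± 0.06). In total 1111 genes were higher and 1091 lower, and 33.0% had no overlap, against 10% by chance. The counts were 1869 and 1894 without the 3 libraries that stood apart. Leaving out 1 library gave from 1192 to 2960 genes, a fit of only the groups compared gave 688, and the highest of 10 simulated draws gave 2996 false calls. Comparisons within vector carry the same risk, since the simulation treated all groups alike.

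The interaction tested whether 2.0 µM FK506 acted differently in A53T and in vector. Gdf15 (-6.83 ± 0.26, adjusted p = 3.0e-08), Tagln (-3.41 ± 0.26) and Cdkn1a (-2.59 ± 0.19) had negative interactions. Glul, the glutamine synthetase of astrocytes (1.61 ± 0.16), Lum (3.29 ± 0.47) and Rcan2 (0.70 ± 0.08) had positive ones. Glul fell in vector from 13270 ± 647 to 5523 ± 510 normalized counts (mean ± SD, n = 3 each), and in A53T its means were 6900 ± 130 in DMSO (n = 2) and 8788 ± 981 at 2.0 µM (n = 3). Of 18 p53 and apoptosis genes 7 had a negative interaction and 0 a positive one (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 1.4e-04, adjusted p = 0.18 with an estimated correlation), including Hrk (-0.62 ± 0.08) and Mdm2 (-0.67 ± 0.13, or adjusted p = 0.0646 with a replicate block by title numbers). At 2.0 µM itself the p53 list did not pass between A53T and vector, with 4 genes higher and 4 lower in A53T. Adjusted over the list alone 4 were higher and 6 lower (camera adjusted p = 0.70, adjusted p = 0.86 with an estimated correlation). Reactive astrocyte genes were negative in 11 of 22 cases and positive in 1 (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.15 with an estimated correlation), including S1pr3 (-1.93 ± 0.20) and Vim (-1.30 ± 0.17).

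Heat shock genes had negative interactions in 6 of 17 cases and positive ones in 0 (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 7.9e-04, adjusted p = 0.23 with an estimated correlation), with Hspa1b (-1.83 ± 0.11). Genes for glutamate and lactate supply by astrocytes were positive in 9 of 21 cases and negative in 1 (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.14 with an estimated correlation), with Pygm (1.29 ± 0.10). Oxidative phosphorylation genes were positive in 11 of 22 cases and negative in 0 (18 higher and 0 lower adjusted over the list alone, camera adjusted p = 3.2e-07, adjusted p = 0.35 with an estimated correlation), with Uqcrc2 (0.38 ± 0.08, or 0.24 and not passed after quantile normalization). This list moved with the axis, and its median went from 0.54 to 0.29 with the score as covariate. In all 916 genes had a positive and 725 a negative interaction, or 2169 and 2085 without the 3 libraries that stood apart. A block by column numbers, which keeps every library, called 1222 in total. The block by title numbers also leaves out the unnumbered library. The total of 1641 became 378 with a replicate block by title numbers and from 632 to 2615 with 1 library left out.

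Effects were then compared between pairs of contrasts that share no library. Over the 1579 genes called for A53T in DMSO, the A53T effect at 0.2 µM had the same sign in 85.5% of cases (r = 0.72 across these genes, slope 0.95). Across all genes r was 0.54. At 2.0 µM the share was 59.1% (r = 0.22, slope 0.15, or -0.00526 in a fit of only the groups compared), and across all genes r was -0.0704. With the axis as covariate the r across all genes was 0.42 for 0.2 µM and 0.16 for 2.0 µM, so the latter turned in sign. Gdf15 was higher with A53T in DMSO and lower at 2.0 µM. Of the 2056 genes called for 0.2 µM FK506 in vector, 89.2% had a fold change of the same sign in A53T, passed or not (r = 0.77). In both, 595 were called higher and 928 lower, where independent lists would share 291 and 407, and 64 were called in opposite directions. Across all genes r was 0.64, or 0.45 with the axis as covariate. Of the 5307 genes called for 2.0 µM FK506 in vector, 80.6% had a fold change of the same sign in A53T (r = 0.67). Across all genes r was 0.48, or 0.63 with the covariate. Of these, 1348 genes were called higher in both, where independent lists would share 519. A further 1185 were called lower in both, against 479, and 119 were called in opposite directions. All calls came from 1 fit with the same spread per gene. Genes with a low spread thus tend to pass in both contrasts, so the numbers for independent lists are too low a baseline at both doses.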

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

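The tests of all 3 patterns weighed here were chosen after the results were seen, and the splits of libraries were planned before. The differences listed were found by the interaction test, which compares the change with FK506 in A53T and in vector. At 0.2 µM it called 5321 genes and at 2.0 µM 1641.

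The A53T libraries at 0.2 µM stood apart from every other group. Their fold change against DMSO had r = 0.792 across genes with the loadings of an axis taken from the other 14 libraries, so part of it runs along variation also seen within groups. Scaling was not its whole cause, since quantile normalization moved the median gene by -0.204 and 6933 of the 7628 genes stayed called, but the share of higher genes went from 49.5% to 40.6%. An exchange of samples is not weighed here. Gene length and the dose itself were not tested, and with 1 sample the biological explanation remains open.

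The p53 and apoptosis genes changed differently at 2.0 µM in A53T and in vector (median interaction -0.36). With the axis as covariate all 7 genes with a negative interaction kept it. The covariate also raised the calls over all genes from 1641 to 2913, so keeping the threshold was favoured. Across genes the interaction and the axis loadings had r = -0.62, so the part of the axis in the size of the difference is not settled. Leaving out any single library kept at least 4 of these 7. The median change at 2.0 µM was 0.97 in vector and 0.40 in A53T, and 8 of 18 genes were already higher in A53T in DMSO. At 2.0 µM itself the list did not pass between A53T and vector (median -0.12, camera adjusted p = 0.70). Of its 18 genes 4 were higher and 4 lower in A53T. The smaller change in A53T thus went with its higher level in DMSO, where it had 2 libraries. Why the change was smaller remains open.

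Reactive astrocyte genes fell with 2.0 µM FK506 in A53T. A lower share of astrocytes alone would lower all astrocyte markers, yet 4 rose past the threshold while 6 fell, and 3 rose after quantile normalization. These rises do not show what lowered the reactive genes. Whether a lower share of astrocytes had a part in their fall is not settled. With the axis as covariate 15 reactive astrocyte genes fell, as without it. An action of the drug on astrocyte state remains a hypothesis, since no separated cell type was measured.

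The other interactions at 2.0 µM were, for genes, Gdf15 -6.83, Tagln -3.41, Cdkn1a -2.59, S1pr3 -1.93, Hspa1b -1.83, Vim -1.30, Mdm2 -0.67, Hrk -0.62, Uqcrc2 0.38, Rcan2 0.70, Pygm 1.29, Glul 1.61, Olig2 1.34, Olig1 2.06 and Lum 3.29. List medians were -0.73 for reactive astrocyte genes, -0.24 for heat shock genes, 0.33 for glutamate and lactate supply by astrocytes, 0.54 for oxidative phosphorylation and 0.28 for lipid droplets and fatty acid oxidation. At 0.2 µM Cacna1e had an interaction of 4.69, Slc1a2 of 3.95 and Gdf15 of -2.19. For 4 comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real split alone reached its count (1 of 10). Other splits called at most 1 gene for A53T against vector at 2.0 µM and 0 for the 3 comparisons within vector. In a wrong split the real group difference counts as spread within groups, so few calls were fixed beforehand and the splits decide nothing. Simulated noise shared along the axis gave up to 2996 false calls for A53T against vector at 2.0 µM. It was drawn alike for all groups, so the comparisons within vector carry the same risk.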

How the results depend on the processing

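The axis covariate, the fit without the 3 libraries that stood apart, the 17-library fit and the block with column numbers were chosen after the results were seen. Of the 120 gene values in the text 113 kept their direction and side of the threshold under every alternative, and none reversed. The naming rule takes large fold changes and small p-values from these same data. This share therefore does not stand for all genes, whose counts moved more. The 7 others missed the threshold in some fit. With a replicate block by title numbers these were Fos and Aldoc for A53T in DMSO, Ppp3ca and Nfatc3 for 2.0 µM in A53T, and Mdm2 and Uqcrc2 for the interaction at 2.0 µM. After quantile normalization Uqcrc2 and Atp5a1 (0.2 µM in vector) missed it. Fos, Ppp3ca, Nfatc3 and Uqcrc2 also did so with a library of A53T in DMSO left out. Of the 56 list results 44 kept theirs, leaving aside the estimated correlation, with which 0 of 177 list calls remained. The lists that did not pass in some fit were astrocyte markers, extracellular matrix and ribosomal genes for A53T at 2.0 µM, GABAergic and pan-neuronal markers and housekeeping genes for 0.2 µM in vector, pan-neuronal markers for 2.0 µM in A53T, housekeeping genes for 0.2 µM in A53T, proliferation and ribosomal genes for 2.0 µM in vector and lipid droplets for the interaction at 2.0 µM. Oligodendrocyte markers, which had not passed, did so in some fits. In a fit of only the groups compared the count of genes was 4174 for A53T against vector in DMSO, 688 at 2.0 µM, and 1786 for 2.0 µM in A53T. With the axis as covariate it was 3842, 3238 and 3900 for A53T against vector in DMSO and at 0.2 and 2.0 µM, 3317 for 0.2 µM and 1695 for 2.0 against 0.2 µM in A53T, 3735 for 0.2 µM in vector, and 2206 and 2913 for the interactions. Without the 3 libraries that stood apart it was 4390 for A53T in DMSO, 3763 for A53T at 2.0 µM, 5897 for 0.2 µM in vector and 4254 for the interaction at 2.0 µM. These 3 were picked for deviating from their groups, so higher counts without them were favoured beforehand. The slope of the A53T effect at 0.2 µM on that in DMSO was 1.45 in a fit of only the groups compared and 1.39 without these libraries, against 0.95. At 2.0 µM the slope of 0.15 became -0.00526 and 0.0144, so its sign turned in the first. The cause of these shifts was not tested.

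With a replicate block by title numbers the counts were 331 for A53T in DMSO, 1574 for 2.0 µM in A53T, 1307 for 0.2 µM in vector, 1721 for the interaction at 0.2 µM and 378 at 2.0 µM. That block also leaves out the unnumbered library, so these counts do not show the effect of blocking alone. A block by column numbers keeps every library. It gave 1162 for A53T in DMSO and 3916 for 2.0 µM in A53T. For 0.2 µM in vector it gave 1729, and for the interaction at 2.0 µM 1222. Same-numbered samples had a median r of -0.107 (22 pairs, 9 over 0.1, highest 0.669), and 5 of 14 samples were closest to their own number. The check cannot exclude pairing, since the axis held 54.2% of the variance compared and the unnumbered sample can match no title number. Leaving out 1 library gave from 413 to 1047 genes for A53T in DMSO, 1192 to 2960 for A53T at 2.0 µM, 980 to 2916 for 0.2 µM in vector, 1837 to 4880 for 2.0 µM in A53T and 632 to 2615 for the interaction at 2.0 µM. The planned edgeR count test was not run, since whole reads were not recovered, and the raw depth is unknown.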

Other observations

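These genes and lists were picked for mention after the results were seen, and no hypothesis was tested on them. Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, responded in opposite directions in the 2 backgrounds. Olig1 fell at 2.0 µM in vector (-1.51 ± 0.07) and rose in A53T (0.54 ± 0.07), with an interaction of 2.06 ± 0.10. Olig2 fell in vector (-0.38 ± 0.08) and rose in A53T (0.96 ± 0.09), with an interaction of 1.34 ± 0.13. Of 12 lineage markers 5 had a positive interaction and 0 a negative one, and the list did not pass (camera adjusted p = 0.064).

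Lipid droplet and fatty acid oxidation genes had a positive interaction in 6 of 19 cases and a negative one in 2 (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.040, adjusted p = 0.44 with an estimated correlation). This list did not pass with the axis as covariate (camera adjusted p = 0.115). Proliferation genes rose in 8 of 18 cases at 2.0 µM in vector and fell in 1 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.34 with an estimated correlation), including the replication clamp Pcna (0.56 ± 0.06) and Mcm2 (0.67 ± 0.09). With the axis as covariate this list did not pass (camera adjusted p = 0.0737). Slc1a2, a glutamate transporter of astrocytes, rose at 0.2 µM in A53T (4.22 ± 0.21), with an interaction of 3.95 ± 0.25. Both values rest on the 1 sample of A53T at 0.2 µM. Across genes the fold changes of that sample against DMSO and the axis loadings had r = 0.79. Slc1a2 does not stand for the 19 measured astrocyte markers. Their median fold change in that comparison was -0.29 (mean 0.08), and the median was -0.36 with the axis as covariate.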
